A study of Homo sapiens with 16 samples.

How the data were processed

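RNA-seq counts of 16 libraries were used, 2 for each of the 8 combinations of cell line (MCF-7 or T47D), construct (pLKO control or UNC5A shRNA, as labelled) and treatment (vehicle or 0.1 nM estradiol for 3 h). Per the labels' protocols, cells were maintained in medium with 10% serum and moved to 5% charcoal-stripped serum without phenol red for 4 days, and total RNA was prepared with a column kit. The groups and replicate numbers come from the sample titles, where a number in brackets marks the second replicate.

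The authors deposited 1 table of raw read counts per library. Per the file headers, reads were counted per gene with bamutils of ngsutils 0.5.7 on a filtered alignment file, with a refGene gene model of hg19, the library type set to FR, so that strand was used, and reads with several alignments handled by the setting called complete. The aligner is not given in the sources used here. The counts cover 26376 genes, of which 5136 had no read in any library, and each row names a gene. Of these, 1411 rows carry a suffix that marks a further copy of a symbol, and counts of such copies, of paralogs and of multigene families such as histones and ribosomal proteins are uncertain where reads could be placed in several copies. The authors also deposited a table of log2 fold changes with p-values made with edgeR, per the submitters' processing notes, whose version is not given in the sources used here. Those log2 values and p-values were used only for the comparison in the last paragraph of the results.

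The deposited counts were tested with edgeR 4.0.16 in R 4.3.3. The low-count filter (filterByExpr on the 8 groups) left 15237 genes, libraries were scaled with TMM, and 1 group-means model with 8 residual degrees of freedom was fitted over all 16 libraries with the quasi-likelihood test (glmQLFit and glmQLFTest, two-sided, Benjamini-Hochberg adjusted p under 0.05). The 12 comparisons were estradiol against vehicle in each of the 4 kinds of cell, UNC5A shRNA against control in each treatment and line, the difference of estradiol responses between shRNA-labelled and control cells in each line, and the differences between lines of the control cells' estradiol response and of the vehicle shRNA effect. Log2 fold changes are given with a standard error, called that of the fit. It was derived as the absolute log2 fold change divided by the square root of the quasi-likelihood F statistic. Group levels are means ± SD of 2 libraries in CPM (counts scaled to a common library size), computed with TMM-scaled library sizes. Ratios of summed counts and folds against the floor are scaled, each sum being divided by the summed TMM-scaled library sizes of its group, so they differ from the plain ratio of reads. Their intervals are exact conditional 95% intervals. A fold against a group with no read is a lower bound from a floor of 3 counts over the group, and with 1 to 3 counts it is a ratio with its interval. Both cover counting error only.

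Gene lists were fixed before the data were examined, together with the design and the rule for named genes, and were tested with camera of limma 3.58.1 on voom log2 CPM with the same design and a preset correlation of 0.01, adjusted over the lists of a comparison. Of 27 lists, 25 had at least 5 tested members. List members were counted over all genes tested and adjusted over the list alone. Camera was repeated with an estimated correlation. The p with an estimated correlation stands beside each camera p that passed. Named genes are, per comparison, up to 10 largest rises and 10 largest falls among called genes with a mean of at least 1 CPM whose groups do not overlap, up to 4 members with the smallest p of each list described, and a fixed set (UNC5A, ESR1, PGR, TFF1, GREB1, TP63, EGFR, KRT14, KRT5, KRT19, BCL2, NTN1 and NTN4). Members outside this rule that are named because a count was 5 or fewer, and those in the 3 plots, were chosen after their values were seen. Overlaps of called genes are given beside n1 × n2 / N.

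Depth was 11137945 to 37140696 counts per library. In data simulated from the real means and library sizes, with 200 genes changed by known folds, the procedure recovered 45% of genes with a log2 fold change of 1 and 90% of those with 2 in the MCF-7 control estradiol comparison (14905 genes tested), 56% and 93% in that of T47D control cells (14912 genes), 54% and 88% in the MCF-7 vehicle shRNA comparison (14897 genes) and 51.5% and 90% in that of T47D (14878 genes). The simulation gave all libraries 1 trend of spread on mean count, with no library set apart and no spread particular to a gene. Only genes above a least mean count in the line were changed. These shares therefore need not hold for the real libraries or for genes with few counts.

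Alternatives fixed before the data were examined were RLE size factors in edgeR, no low-count filter, DESeq2 1.42.0, a fit on the 8 libraries of the one line, the replicate number as a block, robust estimation, each library left out in turn, an estimated correlation for lists and an adjusted p of 0.01 for overlaps. Added after seeing the data were a fit without the 2173 rows of small RNA genes, lists without MCF-7 control vehicle replicate 2, and overlaps of shRNA effects at 0.01. A fit without 1 library leaves a group with 1 sample, which is assumed to vary like the other groups. GC content was that of each gene's longest transcript in a GENCODE annotation of the same build, found for 88.9% of the tested genes. Medians over windows of neighbouring genes were of log2 fold changes with extreme values capped and a smooth trend on GC content removed. They used genes with known GC content and a mean of at least 5 CPM on the numbered chromosomes and X, without small RNA. Coordinates are those of the count files. Figures were drawn with matplotlib 3.10.9.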

Results

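The RNA of MCF-7 and T47D, 2 established human breast cancer lines that express the oestrogen receptor, was measured by RNA-seq. Stable cells carrying the empty vector pLKO (control) were set against stable cells labelled as carrying an shRNA against UNC5A. UNC5A is a netrin receptor of the dependence receptor family, whose members can signal cell death when their ligand is absent. After 4 days in 5% charcoal-stripped serum without phenol red, which lowers oestrogenic activity of the medium, the cells received vehicle or 0.1 nM estradiol for 3 h. This gave 8 groups of 2 libraries, 16 in all. Both shRNA lines carry the designation clone 5, and the labels do not say whether it names a hairpin or a cell clone. Nothing in the labels says that the 2 libraries of a group came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical. Total counts were 11137945 to 17141876 per MCF-7 library and 19293298 to 37140696 per T47D library. Genes of small RNA took 15.7% to 52.3% of the counts. The highest share, 52.3%, was in MCF-7 control vehicle replicate 2, which kept 5621359 counts outside small RNA and had the smallest TMM factor, 0.693. Its 10 most counted genes held 27.5% of its counts. Of the markers of other cell types, 0 of 10 immune markers, 3 of 10 endothelial and adipocyte markers and 5 of 10 fibroblast markers had enough counts to be tested.

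UNC5A itself was at the edge of detection, and its counts did not follow the labels in MCF-7. The gene lies on chromosome 5, 176237560 to 176307899, plus strand of hg19, with 3733 bases of exon in the annotation. In vehicle the MCF-7 libraries labelled UNC5A shRNA held 16 and 19 UNC5A reads, 1.05 ± 0.0693 CPM (SD, n = 2), against 1 and 7 reads, 0.46 ± 0.562 CPM, in the control. The ratio of summed counts, shRNA over control, each sum first divided by the summed TMM-scaled library sizes of its group, was 3.17 with an exact 95% interval of 1.44 to 7.9, which covers counting error only. In estradiol the MCF-7 counts were 8 and 21 against 2 and 6, a scaled ratio of 2.13 (0.95 to 5.39). In T47D vehicle they were 9 and 14 in the libraries labelled UNC5A shRNA, 0.49 ± 0.217 CPM, against 40 and 19 in the control, 1.24 ± 0.306 CPM. That scaled ratio was 0.37 (0.218 to 0.609). In T47D estradiol, 20 and 9 reads against 18 and 5, in smaller libraries, gave a scaled ratio of 0.921 (0.515 to 1.67). Estradiol over vehicle gave scaled UNC5A ratios of 1.06 (0.347 to 3.24) in MCF-7 control cells, 0.714 (0.421 to 1.2) in MCF-7 shRNA-labelled cells, 0.391 (0.23 to 0.642) in T47D control cells and 0.972 (0.543 to 1.76) in T47D shRNA-labelled cells. None of these UNC5A differences passed edgeR's quasi-likelihood test, with adjusted p of 0.279 and 0.467 for the label in MCF-7, 0.411 and 0.922 in T47D, and 0.836 to 1 for estradiol. Without MCF-7 control vehicle replicate 2 the UNC5A difference in MCF-7 vehicle stood at a log2 fold change of 3.98, upwards. The control is then 1 library with 1 UNC5A read, so the size of this value is very uncertain. Directions drawn from the shRNA label in MCF-7 therefore rest on the label and not on a lower UNC5A count. The same holds for T47D in estradiol, and in T47D vehicle the lower count did not pass the test.

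**Figure D1:**
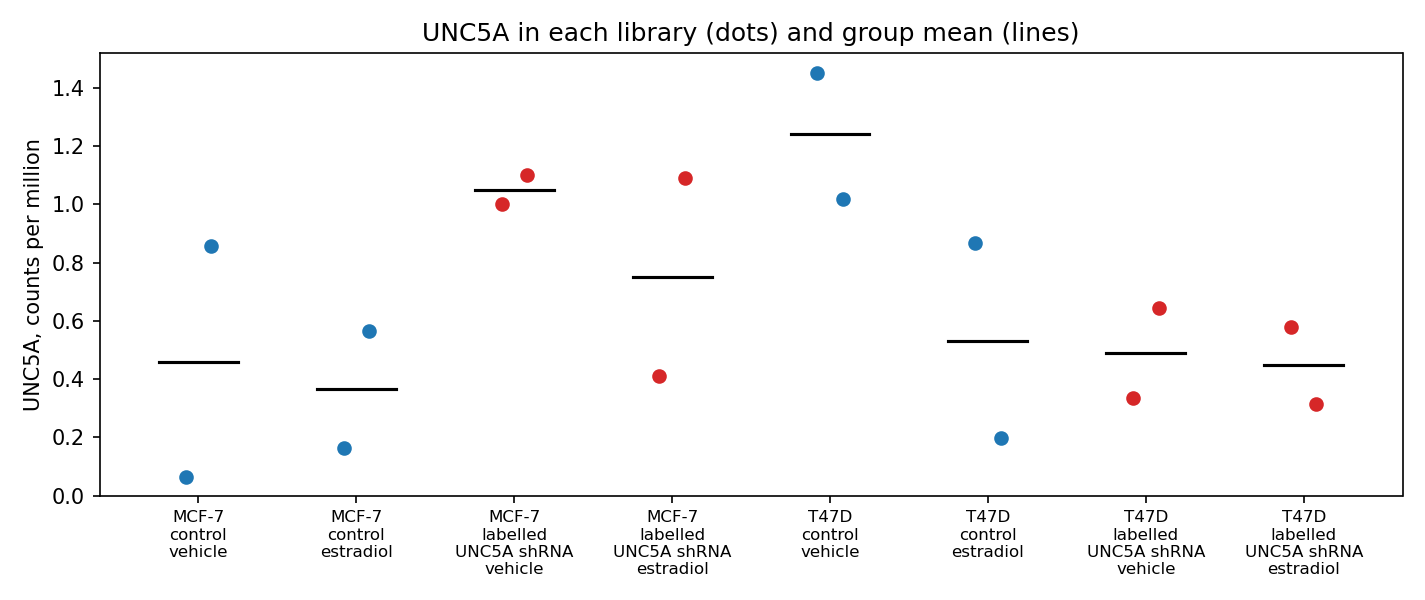
UNC5A in CPM (vertical axis) in each of the 16 libraries (dots, blue for control and red for libraries labelled UNC5A shRNA) by group, with black lines at the group means. In MCF-7 vehicle both libraries labelled UNC5A shRNA lie above both control libraries, and in T47D vehicle both lie below.

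In MCF-7 control cells, 3 h of estradiol raised well-known oestrogen target genes, which addresses how these cells respond to the hormone. GREB1, a cofactor of the oestrogen receptor (chromosome 2, 11674242 to 11782912, plus strand), went from 36.6 ± 6.1 to 248 ± 16 CPM (SD, n = 2), a log2 fold change of 2.77 (SE 0.169, adjusted p = 6.4e-07). CA12, a carbonic anhydrase, rose by 2.75, SIAH2, a ubiquitin ligase, by 2.36, CCND1, which encodes cyclin D1, by 1.85 and RET, a receptor tyrosine kinase that is itself a dependence receptor, by 3.48. Of 48 tested genes on the estradiol-induced list 32 rose and 0 fell, or 38 and 0 adjusted over the list alone. The list moved up against all other genes (camera, adjusted p = 1.86e-53, and adjusted p = 4.46e-05 with an estimated correlation). Of 36 ribosome biogenesis genes 8 rose and 0 fell (14 and 0 adjusted over the list alone), among them the RNA helicases DDX10 (1.37) and DDX21 (1.15) and POLR1B, a subunit of RNA polymerase I (1.10). Their camera adjusted p was 3.56e-10, and adjusted p = 0.0225 with an estimated correlation. Among 23 immediate early genes 4 rose, including FOS (2.39), MYC (2.04) and EGR3 (4.95), with a camera adjusted p of 0.0465 and an adjusted p of 0.493 with an estimated correlation. FOS, MYC and EGR3 are also on the estradiol-induced list, so the 2 list results are not separate. Of 22 estradiol-repressed genes 3 fell and 1 rose (11 and 2 adjusted over the list alone). Those that fell were BMF, a pro-apoptotic BH3-only protein (−1.98), TGFB3 (−1.26) and CCNG2, a cyclin linked to cell cycle arrest (−1.10). The call of CCNG2 was lost without control estradiol replicate 1, where it stood at −0.90. The gene that rose was CYP1B1 (0.85), whose call was lost when any of 8 libraries was left out. That list had a camera adjusted p of 2.72e-05, downwards, and an adjusted p of 0.229 with an estimated correlation, and 7 of its genes fell and 0 rose without control vehicle replicate 2. RNF43, a ubiquitin ligase that restrains Wnt receptors, fell by 2.58 on the log2 scale. TGM2 and SEMA3G had no read in vehicle and were at least 22.3-fold and 18.4-fold higher in estradiol, taking 3 counts over the group as the floor.

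In all, 267 genes rose and 113 fell in the MCF-7 control cells, of 15237 tested (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p under 0.05). The progesterone receptor gene PGR, a classical target, had a log2 fold change of 0.22 (SE 0.469, adjusted p = 0.836), with 8.59 and 44.2 CPM in control vehicle replicates 1 and 2, and 1.85 without replicate 2, past the threshold. TFF1, another target, stood at 1.38 (adjusted p = 0.0453), a call lost when any of 12 libraries was left out. Ribosomal protein genes were lower as a list (0 of 50 called, camera adjusted p = 0.0106, adjusted p = 0.736 with an estimated correlation), and higher without control vehicle replicate 2, the library richest in small RNA (adjusted p = 1.9e-06). Replication-dependent histone genes were lower as a list (0 of 19 called, 2 adjusted over the list alone, camera adjusted p = 0.0106, adjusted p = 0.643 with an estimated correlation), a call lost without that library (adjusted p = 0.0643). The number of genes called ran from 96 without control estradiol replicate 2 to 4455 without control vehicle replicate 1, and was 340 without control vehicle replicate 2.

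In the MCF-7 cells labelled UNC5A shRNA, estradiol raised genes of the estradiol-induced and ribosome biogenesis lists and lowered estradiol-repressed genes. GREB1 went from 50.7 ± 4.37 to 358 ± 24.3 CPM, a log2 fold change of 2.82 (SE 0.168, adjusted p = 3.39e-07). MYC rose by 2.98, RAPGEFL1, a guanine exchange factor gene, by 3.53, CA12 by 2.55, the potassium channel gene KCNK5 by 4.49, EGR3 by 5.01 and SMTNL2 by 6.34. Of the 48 estradiol-induced genes 38 rose and 0 fell, or 40 and 1 adjusted over the list alone (camera adjusted p = 5.85e-56, adjusted p = 3.78e-05 with an estimated correlation). Of the 36 ribosome biogenesis genes 23 rose and 0 fell (29 and 0 adjusted over the list alone), with DDX10 at 1.67, POLR1B at 1.39 and WDR43 at 1.34 (camera adjusted p = 3.05e-26, adjusted p = 0.000919 with an estimated correlation). Of the 22 estradiol-repressed genes 10 fell, or 12, with 1 that rose, adjusted over the list alone. They included CCNG2 (−2.21), TP53INP1, a p53 target (−1.61), the KIT ligand gene KITLG (−1.49), TGFB3 (−1.14) and BIK, a pro-apoptotic BCL2 family gene (−1.92). The list's camera adjusted p was 1.76e-07, and adjusted p = 0.104 with an estimated correlation. FKBP4 (1.26) and AHSA1 (0.91), co-chaperone genes of HSP90, were the 2 of 15 heat shock genes that rose (9 adjusted over the list alone, camera adjusted p = 2.19e-05, adjusted p = 0.146 with an estimated correlation), and 6 rose without control vehicle replicate 2. Of 50 ribosomal protein genes 3 rose, RPL3 (0.76), RPL23 (0.73) and RPS25 (0.92), and 8 without control vehicle replicate 2 (3 adjusted over the list alone, camera adjusted p = 0.000359, adjusted p = 0.895 with an estimated correlation). AHSA1 and these 3 lost their calls without any of the 4 libraries of the comparison, and RPL23 and RPS25 also without certain T47D libraries. Of 26 apoptosis genes 4 rose, such as the survival gene BIRC3 (1.65) and the pro-apoptotic PMAIP1 (1.80), and 2 fell (5 and 3 adjusted over the list alone, camera adjusted p = 0.978). Of 25 luminal genes 5 rose, such as XBP1 (1.70), KRT18 (1.32) and ELF3 (1.16), and 1 fell, GATA3 (−1.27), or 7 and 5 adjusted over the list alone and 7 and 6 without control vehicle replicate 2, and the list did not pass camera (adjusted p = 0.787). ELF3 lost its call without shRNA vehicle replicate 2, at 0.99, and GATA3 without that library, at −1.11, or either shRNA estradiol replicate. Of 23 immediate early genes 4 rose and 3 fell (6 and 4 adjusted over the list alone, camera adjusted p = 0.265). SPEG and LOXL4 had no read in vehicle and were at least 25-fold and 18.4-fold higher in estradiol. TFF1 rose by 2.19 (adjusted p = 0.00115) and PGR by 1.90 (adjusted p = 0.0291), the latter a call lost without any of the 4 libraries of the comparison. Altogether 500 genes rose and 267 fell, and the 767 ran from 315 without shRNA vehicle replicate 2 to 1608 without control vehicle replicate 2.

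Whether the label changed the estradiol response in MCF-7 was tested as the difference of the responses, shRNA-labelled minus control, and 4 genes passed. The sphingosine phosphate transporter gene SPNS2 (chromosome 17, 4402129 to 4443228, plus strand) differed by 4.29 (SE 0.581, adjusted p = 0.0305). It went from 4.17 ± 1.38 to 4.52 ± 0.154 CPM in control cells and from 0.212 ± 0.0542 to 4.7 ± 0.973 CPM in shRNA-labelled cells. TBKBP1, which encodes a binding partner of the kinase TBK1, differed by 3.36, the prostaglandin E synthase gene PTGES by 1.76 and GLCCI1 by −1.70. GREB1 differed by 0.06 (SE 0.225, adjusted p = 0.956), TFF1 by 0.81 (adjusted p = 0.458) and PGR by 1.68 (adjusted p = 0.305). TFF1 and PGR passed without control vehicle replicate 1, at 1.23 and 2.46, and stood at 0.21 and 0.04 without replicate 2. The ribosome biogenesis list, which was lower in shRNA-labelled cells in vehicle, moved further up in them (0 of 36 called, 11 adjusted over the list alone, camera adjusted p = 2.37e-07, and adjusted p = 0.12 with an estimated correlation). The estradiol-induced list did so at a camera adjusted p of 0.035 (0 of 48 called, 8 higher and 2 lower adjusted over the list alone), with an adjusted p of 0.231 without control vehicle replicate 2 and an adjusted p of 0.744 with an estimated correlation. Ribosomal protein, heat shock and histone genes also stood higher as lists (0 called, 5, 3 and 1 adjusted over the list alone, camera adjusted p = 2.37e-07, 0.0265 and 0.0265), each with an adjusted p of 0.744 with an estimated correlation. Without control vehicle replicate 2 these were 0.978, 0.000286 and 0.191, which ends the first and the last call. The number of genes ran from 0, without control estradiol replicate 1 among others, to 3021 without control vehicle replicate 1, and was 32 without control vehicle replicate 2. Each of the 4 calls was lost without control estradiol replicate 1, among other libraries, and 2048 genes had an unadjusted p under 0.05.

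**Figure D2:**
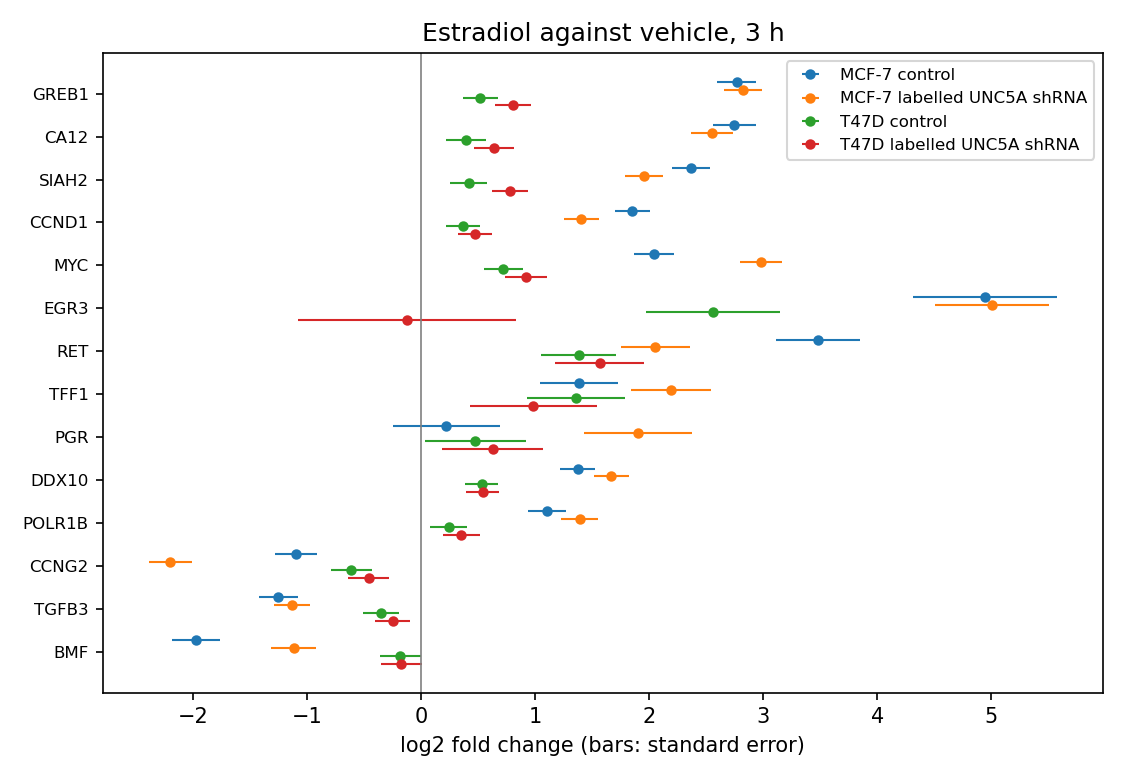
Log2 fold change of estradiol over vehicle (horizontal axis, bars give the standard error of the fit) for 14 genes in the 4 kinds of cell, MCF-7 in blue and orange, T47D in green and red. GREB1 lies at 2.77 and 2.82 in MCF-7 and at 0.52 and 0.81 in T47D.

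Few genes passed the test in T47D. In control cells 9 genes rose and 0 fell, and in cells labelled UNC5A shRNA 7 rose and 0 fell, with 980 and 480 genes at an unadjusted p under 0.05 and 45 and 39 genes called by DESeq2. RASGRP1, a Ras exchange factor gene (chromosome 15, 38780302 to 38857007, minus strand), went from 1.53 ± 0.411 to 7.02 ± 2.17 CPM in control cells, a log2 fold change of 2.18 (SE 0.296, adjusted p = 0.0157). In shRNA-labelled cells it rose by 2.39 (SE 0.291, adjusted p = 0.00826). MAP6D1 rose by 1.44 and 1.2, and PFKFB3, a regulator of glycolysis, by 1.22 and 1.13. These 3 genes were called in both. RAPGEFL1 (1.42), HSPB8, a small heat shock protein gene (1.21), NXPH3 (2.26), B4GALT1 (1.27) and PTGES (1.02) rose in control cells, and NPY1R, a neuropeptide Y receptor gene (1.54), FMN1 (1.18), PPP2R2C (1.17) and ITPK1 (1.12) in shRNA-labelled cells. GREB1 had 0.52 (SE 0.157, adjusted p = 0.56) and 0.81 (SE 0.157, adjusted p = 0.119), and the latter passed at a nearly equal value without either MCF-7 control vehicle library, 0.81 without replicate 1 and 0.80 without replicate 2. Of 48 estradiol-induced genes 2 and 0 were called, or 20 and 25 adjusted over the list alone, all of them higher. Without MCF-7 control vehicle replicate 2, 6 and 11 were called. That list moved up in control cells (camera adjusted p = 8.14e-27, adjusted p = 0.000588 with an estimated correlation) and in shRNA-labelled cells (2.16e-50, and adjusted p = 5.59e-05 with an estimated correlation). Ribosome biogenesis genes moved up as a list in control cells (0 of 36 called, 2 adjusted over the list alone, camera adjusted p = 7.27e-11, adjusted p = 0.0178 with an estimated correlation) and in shRNA-labelled cells (0 called, 3 adjusted over the list alone, 3.12e-13, adjusted p = 0.0096 with an estimated correlation). Estradiol-repressed genes moved down in control cells (0 of 22 called, 4 adjusted over the list alone, 4.57e-10, adjusted p = 0.045 with an estimated correlation) and in shRNA-labelled cells (0 called, 0 adjusted over the list alone, 3.04e-08, adjusted p = 0.0588 with an estimated correlation), and 3 were called in control cells without MCF-7 control vehicle replicate 2. The unfolded protein response list moved up in control cells (0 of 23 called, 0 adjusted over the list alone, 0.000597, adjusted p = 0.047 with an estimated correlation) and in shRNA-labelled cells (0 and 0 again, 0.000798, adjusted p = 0.0569 with an estimated correlation). With 0 members called, and 0 adjusted over the list alone, proliferation genes moved up in both (0.000544 and 0.0351, adjusted p = 0.316 and 0.5 with an estimated correlation), ribosomal protein genes up in control cells (4.25e-06, adjusted p = 0.499 with an estimated correlation, 1 called without MCF-7 control vehicle replicate 2) and interferon response genes down in shRNA-labelled cells (0.00492, adjusted p = 0.34 with an estimated correlation). The difference of the T47D responses gave 0 genes by edgeR, 0 by DESeq2 and 248 at an unadjusted p under 0.05. These 248, and the 480 in shRNA-labelled cells, are fewer than 0.05 of the 15237 genes tested, the number expected with no effect. The edgeR test was therefore conservative there, and few or 0 calls do not show a weak or unchanged response. Of the lists, ribosomal protein genes passed for that difference, downwards (0 of 50 called, 0 adjusted over the list alone, median log2 difference −0.28, camera adjusted p = 9.86e-05, adjusted p = 0.598 with an estimated correlation). Calls in T47D control cells ran from 0 without T47D control vehicle replicate 2 to 48 without MCF-7 control vehicle replicate 1, and in shRNA-labelled cells from 0 without T47D shRNA vehicle replicate 1 to 40 without MCF-7 control vehicle replicate 1. Each of the calls named was lost in at least 1 of these fits.

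Between the lines, the control cells' estradiol responses differed for 33 genes, 29 with a larger and 4 with a smaller log2 fold change in MCF-7. GREB1 differed by 2.25 (SE 0.226, adjusted p = 0.000339), the sulfate transporter gene SLC26A2 by 2.64, CA12 by 2.35 and SIAH2 by 1.95. CCND1 (1.49) and the nuclear receptor gene NR5A2 (2.94) passed as well, and both calls were lost without T47D control estradiol replicate 1. The 4 lower in MCF-7 were RIMS2 (−3.57), RNF43 (−1.80), BMF (−1.80) and PPP1R3C (−1.59). Each of these 4 lost its call without some library, RIMS2, BMF and PPP1R3C without MCF-7 control estradiol replicate 2 among them and RNF43 without either control estradiol replicate of MCF-7. GREB1 in vehicle was higher in T47D, 203 ± 3.94 CPM against 36.6 ± 6.1 in MCF-7. Of the 48 estradiol-induced genes 7 differed, all larger in MCF-7 (24 larger and 1 smaller adjusted over the list alone, camera adjusted p = 1.03e-21, adjusted p = 0.00167 with an estimated correlation), and 11 without MCF-7 control vehicle replicate 2. Ribosomal protein, proliferation and histone genes stood lower in MCF-7 as lists (0 called, 0, 0 and 4 adjusted over the list alone, camera adjusted p = 1.44e-06, 0.0288 and 0.00444), each with an adjusted p of 0.538 with an estimated correlation, and the first lost its call without MCF-7 control vehicle replicate 2 (adjusted p = 0.933). TFF1 differed by 0.02 (SE 0.641) and PGR by −0.26 (SE 0.646). PGR passed without MCF-7 control vehicle replicate 1, at −1.03, and stood at 1.40 without replicate 2, where it did not pass. The 33 ran from 7 without T47D control estradiol replicate 1 to 3847 without MCF-7 control vehicle replicate 1. Within MCF-7, 165 genes rose and 35 fell in both kinds of cell, against 8.76 and 1.98 for independent lists, and 1 moved in opposite directions. Of the genes that rose in T47D, 6 also rose in MCF-7 in control cells (0.158 by chance) and 6 in shRNA-labelled cells (0.23 by chance). None of these pairs shares a library.

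Vehicle libraries labelled UNC5A shRNA were set against the control to see how the cells differed by label before hormone was given. In MCF-7, where UNC5A was not lower, this is a comparison by label and not for loss of UNC5A. BCL2, an anti-apoptotic gene (chromosome 18, 60790579 to 60986613, minus strand), was at 21.3 ± 4.89 CPM against 1.21 ± 0.502 (SD, n = 2), a log2 fold change of 4.04 (SE 0.305, adjusted p = 1.08e-07). KITLG (chromosome 12, 88886570 to 88974250, minus strand) was higher by 4.16 (SE 0.213, adjusted p = 2.07e-09) and ELOVL2, a fatty acid elongase gene, by 5.23. EPHA4, an ephrin receptor gene (chromosome 2, 222282747 to 222437010, minus strand), was lower, 7.94 ± 0.452 against 289 ± 138 CPM, a log2 fold change of −5.18 (SE 0.29, adjusted p = 4.63e-09). Of 19 dependence receptor and netrin genes 6 rose and 2 fell, the same counts adjusted over the list alone, with RET at 3.21, the netrin receptor gene UNC5C at least 75-fold higher, NTN4 at 1.28 and netrin 1 (NTN1) at −1.63. That list did not pass camera (adjusted p = 0.223). Of 25 luminal genes 12 rose, such as ERBB4 (2.17), the prolactin receptor PRLR (1.75) and ESR1, the oestrogen receptor (0.83), and 5 fell, KRT18 (−1.58) among them. The counts were 13 and 6 adjusted over the list alone, with a camera adjusted p of 0.0429 and an adjusted p of 0.27 with an estimated correlation, and 13 rose and 3 fell without control vehicle replicate 2. KRT19, also luminal, stood at −1.31 (adjusted p = 0.0058) and at −0.54 without control vehicle replicate 2, where the call was lost. Of 31 basal genes 7 rose and 11 fell (8 and 11 adjusted over the list alone), with caveolins CAV1 (−5.64) and CAV2 (−2.96), TAGLN (−6.41) and ANXA3 (−2.71) lower and TP63, a basal transcription factor, higher by 2.07. TP63 lost its call without shRNA vehicle replicate 2, at 1.33. The basal list did not pass camera (adjusted p = 0.189). KRT5 (−0.27, adjusted p = 0.637), KRT14 (−0.29, adjusted p = 0.824) and EGFR (0.29, adjusted p = 0.638) did not pass.

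Also in MCF-7 vehicle, 25 of 50 proliferation genes rose and 7 fell (28 and 7 adjusted over the list alone), with the mitotic kinase AURKA at 1.76, CENPF at 1.75 and MKI67 at 1.70 (camera adjusted p = 7.16e-05, adjusted p = 0.27 with an estimated correlation), and 25 and 4 without control vehicle replicate 2. Of 26 hypoxia genes 3 rose and 14 fell (4 and 14 adjusted over the list alone), with DDIT4 at −2.06, VEGFA at −1.43 and the glucose transporter SLC2A1 at −1.25 (camera adjusted p = 0.00542, adjusted p = 0.214 with an estimated correlation). Of 50 ribosomal protein genes 0 rose and 37 fell (0 and 40 adjusted over the list alone), such as RPL3 (−1.79) and RPS8 (−1.95). Without control vehicle replicate 2, the library with 52.3% small RNA, 2 rose and 20 fell. The list's camera adjusted p was 2.36e-09, and adjusted p = 0.438 with an estimated correlation. Ribosome biogenesis genes fell too, 22 of 36 with 1 that rose (24 and 2 adjusted over the list alone), such as NOP2 (−1.79) and DKC1 (−1.57), at a camera adjusted p of 6.36e-06 and an adjusted p of 0.214 with an estimated correlation. Of 25 cholesterol synthesis genes 3 rose and 8 fell (3 and 8 adjusted over the list alone), at a camera adjusted p of 0.0466, downwards, and an adjusted p of 0.27 with an estimated correlation, a call lost without control vehicle replicate 2 (adjusted p = 0.062). Several genes were present in one kind of MCF-7 cell and nearly absent from the other. The matrix protein gene TNC (chromosome 9, 117781854 to 117880536, minus strand) was at 0.452 ± 0.0675 CPM in shRNA-labelled cells and 482 ± 20.1 in the control. CDKN2B, which encodes a cell cycle inhibitor, was lower, at a log2 fold change of −7.90. RAB34 was 1150-fold lower (counting interval 318 to 9520) and the LDL receptor regulator PCSK9 1900-fold lower (340 to 75000). The protocadherin gene PCDH10 was at least 580-fold higher, and EPHA3 at least 109-fold. Of 12 stem and progenitor genes 4 rose and 3 fell, the same adjusted over the list alone, and the list did not pass camera (adjusted p = 0.326). The stem cell factor SOX2 (4.64) and TWIST1, a transcription factor of epithelial-mesenchymal transition (3.85), were higher, and TGFB2 (−5.62) was lower. In total 2721 genes were higher and 3019 lower. The 5740 ran from 3673 without shRNA vehicle replicate 2 to 7003 without control vehicle replicate 1.

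In estradiol the same MCF-7 contrast gave 2248 genes higher and 2229 lower. Of these, 1563 were higher and 1643 lower in vehicle too, against 401 and 442 for independent lists. BCL2 was higher by 4.13 (SE 0.284, adjusted p = 4.3e-08), ELOVL2 by 6.26, ERBB4 by 1.95, NTN4 by 1.25 and TP63 by 2.08. CAV1 (−6.26), TAGLN (−5.85) and TNC (−10.77) were lower. Of 19 dependence receptor and netrin genes 5 rose and 2 fell (5 and 3 adjusted over the list alone, camera adjusted p = 0.548), and of 31 basal genes 6 rose and 11 fell (7 and 11 adjusted over the list alone, camera adjusted p = 0.35). Of 50 proliferation genes 30 rose and 3 fell (33 and 5 adjusted over the list alone), such as AURKA (1.83) and NUSAP1 (1.64), with a camera adjusted p of 9.25e-07 and an adjusted p of 0.245 with an estimated correlation, and 33 rose and 5 fell without control vehicle replicate 2. Of 25 luminal genes 7 rose, such as MLPH (1.80), and 3 fell, ERBB3 (−0.88), KRT8 (−0.74) and KRT18 (−0.60), or 9 and 3 adjusted over the list alone (camera adjusted p = 0.0439, adjusted p = 0.412 with an estimated correlation). KRT8 lost its call without shRNA estradiol replicate 1 and KRT18 without any of 7 libraries. Of 19 histone genes 6 rose and 0 fell, the same adjusted over the list alone (camera adjusted p = 0.0439, adjusted p = 0.628 with an estimated correlation). Of 26 hypoxia genes 1 rose and 15 fell (2 and 18 adjusted over the list alone), such as DDIT4 (−2.38) and LDHA (−1.18), at a camera adjusted p of 0.00107 and an adjusted p of 0.181 with an estimated correlation. Of 35 interferon response genes 12 rose and 2 fell (13 and 2 adjusted over the list alone), such as OAS3 (3.04) and SAMD9 (2.36), at a camera adjusted p of 0.0439 and an adjusted p of 0.628 with an estimated correlation. Ribosomal protein genes fell, 11 of 50 (8 adjusted over the list alone), such as RPL5 (−0.99), at a camera adjusted p of 0.00146 and an adjusted p of 0.735 with an estimated correlation, and 21 fell without control vehicle replicate 2. Ribosome biogenesis genes had a median log2 fold change of −0.16 in this contrast without control vehicle replicate 2, against −0.605 in vehicle. HPGD, which degrades prostaglandins, had no read in shRNA-labelled cells and was at least 412-fold lower, and ZNF486 was at least 147-fold higher. ESR1 (0.51, adjusted p = 0.0582) and EGFR (−0.03, adjusted p = 0.982) did not pass. ESR1 passed without either MCF-7 control vehicle library, at 0.51 without replicate 1 and 0.49 without replicate 2. The 4477 ran from 2695 without shRNA estradiol replicate 2 to 5903 without control vehicle replicate 2.

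In T47D vehicle, interferon response genes were higher in the libraries labelled UNC5A shRNA. UNC5A counts were lower there, but that difference did not pass edgeR's quasi-likelihood test (adjusted p = 0.411), so this too is a comparison by label. IFIT1, an interferon-induced antiviral gene (chromosome 10, 91152303 to 91166244, plus strand), was at 109 ± 18.2 CPM against 9.52 ± 1.6, a log2 fold change of 3.52 (SE 0.38, adjusted p = 3.6e-05). Of 35 interferon response genes 20 rose and 0 fell (27 and 0 adjusted over the list alone), with ISG15 at 3.30, PARP9 at 1.39 and IFIT5 at 1.24. The list passed camera (adjusted p = 1.38e-19, adjusted p = 0.0106 with an estimated correlation). BCL2 rose here as well, from 3.07 ± 0.234 to 25.5 ± 0.455 CPM, by 3.05 (SE 0.257, adjusted p = 2.67e-06). The amino acid transporter gene SLC7A5 rose by 2.35, and MYC (chromosome 8, 128748315 to 128753680, plus strand) fell by 2.19 on the log2 scale. Of 48 estradiol-induced genes 4 rose and 14 fell (6 and 24 adjusted over the list alone), at a camera adjusted p of 0.000498, downwards, and an adjusted p of 0.123 with an estimated correlation. Of 19 dependence receptor and netrin genes 3 rose and 4 fell (4 and 4 adjusted over the list alone), with NTN4 (2.23) and EPHA4 (1.95) higher and the netrin receptors NEO1 (−1.85) and UNC5C (−2.72) lower, and the list did not pass camera (adjusted p = 0.901). Of 25 cholesterol synthesis genes 0 rose and 6 fell (1 and 8 adjusted over the list alone), such as the LDL receptor LDLR (−1.22), at a camera adjusted p of 0.000278 and an adjusted p of 0.102 with an estimated correlation. Of 36 ribosome biogenesis genes 2 rose, DKC1 (0.74) and HEATR1 (0.64), and 0 fell, the same adjusted over the list alone (camera adjusted p = 0.00328, adjusted p = 0.198 with an estimated correlation), and both lost their calls without control vehicle replicate 1 or shRNA vehicle replicate 1. Of 14 Wnt targets 1 rose, the Wnt inhibitor DKK1 (4.50), and 3 fell, MYC, LEF1 (−3.31) and BMP4 (−1.24). Adjusted over the list alone 1 rose and 5 fell, and the camera adjusted p was 0.00161, or adjusted p = 0.107 with an estimated correlation. BMP4 lost its call without shRNA vehicle replicate 1, at −1.08. Of 31 basal genes 2 rose, TP63 (1.73, adjusted p = 0.0268) and DST (0.98), and 2 fell, KRT15 (−1.87) and ITGB4 (−0.91). The counts were 2 and 3 adjusted over the list alone, with a camera adjusted p of 0.901. TP63 lost its call without any of the 4 libraries of the comparison, and ITGB4 without control vehicle replicate 1 or shRNA vehicle replicate 1. Of 25 luminal genes 1 rose, BCL2, and 1 fell, TFF3 (−2.90), or 1 and 2 adjusted over the list alone, with a camera adjusted p of 0.336. ESR1 (−0.32, adjusted p = 0.378), EGFR (0.62, adjusted p = 0.453), GREB1 (−0.25, adjusted p = 0.4) and PGR (−0.09, adjusted p = 0.95) did not pass. Without MCF-7 control vehicle replicate 2, 1 cholesterol synthesis gene rose and 10 fell, 9 ribosome biogenesis genes rose, 5 Wnt targets fell, 3 basal genes rose and 4 fell, and 2 luminal genes rose and 4 fell. TMTC1 (7.15) and the potassium channel gene KCNJ2 (7.10) rose, and ITM2A (−3.67) fell. In total 574 genes rose and 503 fell, and the 1077 ran from 401 without T47D control vehicle replicate 1 to 2101 without MCF-7 control vehicle replicate 2.

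**Figure D3:**
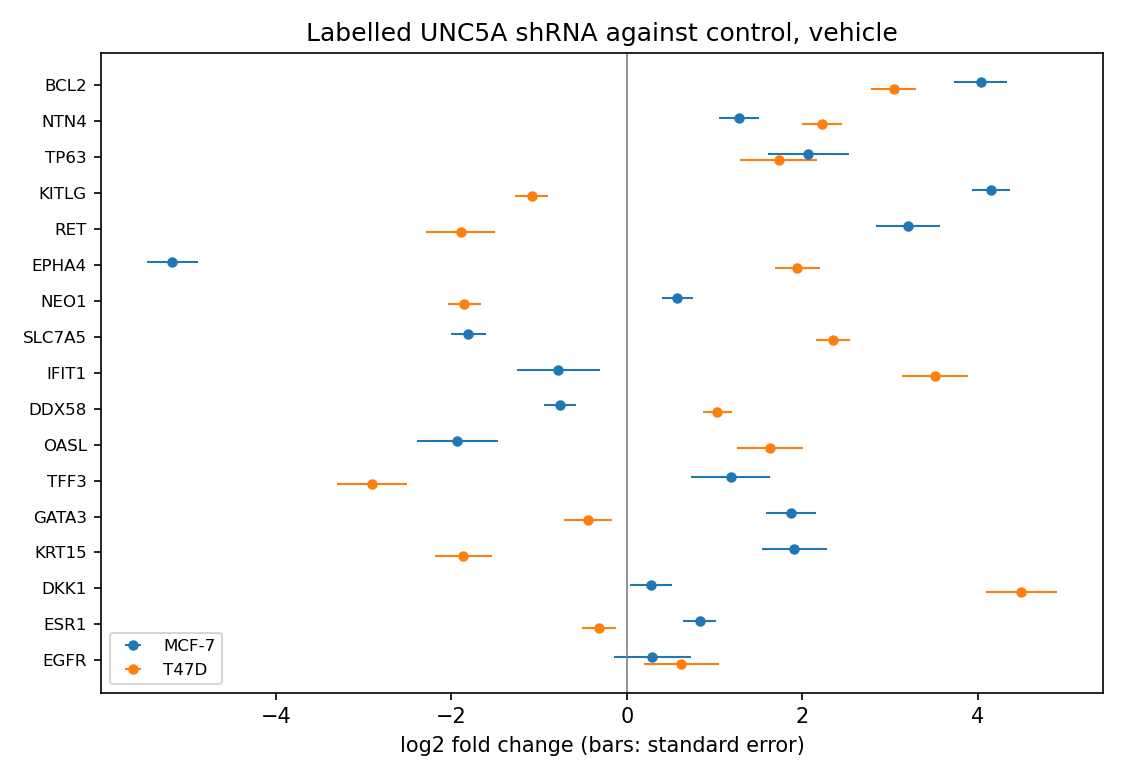
Log2 fold change of libraries labelled UNC5A shRNA over control in vehicle (horizontal axis, bars give the standard error of the fit) for 17 genes, MCF-7 in blue and T47D in orange. BCL2 lies at 4.04 and 3.05, and EPHA4 at −5.18 in MCF-7 and 1.95 in T47D.

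T47D in estradiol gave 775 genes higher and 725 lower, of which 451 and 375 moved the same way in vehicle, against 29.2 and 23.9 for independent lists. UNC5A was not clearly lower in this comparison, at a scaled ratio of 0.921 (0.515 to 1.67), so the directions rest on the label. IFIT1 was higher by 3.12 (SE 0.374, adjusted p = 7.89e-05), and 19 of 35 interferon response genes rose with 0 falls (24 and 0 adjusted over the list alone, camera adjusted p = 2.1e-15, adjusted p = 0.0267 with an estimated correlation). BCL2 (3.12), SLC7A5 (1.84), NTN4 (2.14) and EPHA4 (2.42) were higher, and MYC (−1.99), NEO1 (−2.24) and TFF3 (−2.97) were lower. Of 19 dependence receptor and netrin genes 3 rose and 4 fell, the same adjusted over the list alone (camera adjusted p = 0.901), of 25 luminal genes 2 and 2 (3 and 6 adjusted over the list alone, 0.295) and of 31 basal genes 2 and 3 (3 and 5 adjusted over the list alone, 0.901). Of 25 cholesterol synthesis genes 0 rose and 8 fell (0 and 14 adjusted over the list alone), with LDLR at −1.22, a camera adjusted p of 3.22e-05 and an adjusted p of 0.0491 with an estimated correlation. Of 48 estradiol-induced genes 5 rose and 14 fell (8 and 15 adjusted over the list alone, camera adjusted p = 0.0135, downwards, adjusted p = 0.289 with an estimated correlation). Of 14 Wnt targets 1 rose, DKK1 (3.18), and 2 fell, MYC and LEF1 (−2.97), or 1 and 3 adjusted over the list alone, at a camera adjusted p of 0.0379, downwards, and an adjusted p of 0.289 with an estimated correlation. Of 16 genes of EGFR and ERBB signalling 3 rose, NRG4 (3.56), SPRY1 (1.32) and SPRED1 (0.95), or 6 adjusted over the list alone (camera adjusted p = 0.0135, adjusted p = 0.31 with an estimated correlation), and these 3 lost their calls without T47D control estradiol replicate 1, among other libraries. Of 36 ribosome biogenesis genes 6 rose and 1 fell (9 and 3 adjusted over the list alone, camera adjusted p = 0.0406, adjusted p = 0.332 with an estimated correlation). Without MCF-7 control vehicle replicate 2, 14 cholesterol synthesis genes fell, 4 luminal genes rose and 7 fell, 3 basal genes rose and 6 fell, 8 estradiol-induced genes rose, 6 EGFR and ERBB genes rose, 10 ribosome biogenesis genes rose and 3 fell, and the Wnt targets, 2 higher and 3 lower, no longer passed (adjusted p = 0.0544). TP63 was higher by 2.33 (adjusted p = 0.00811), a call lost without either control estradiol replicate of T47D. FOXR2, a forkhead gene, had no read in the control and was at least 335-fold higher. The 1500 ran from 403 without T47D shRNA estradiol replicate 1 to 3170 without MCF-7 control vehicle replicate 2.

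The vehicle differences between shRNA-labelled and control cells were not alike in the lines. Called genes moved the same way in 127 cases upwards (103 by chance) and 150 downwards (99.7), and in opposite directions in 298 (204), and log2 fold changes correlated across genes at r = −0.019 and rho = 0.016, where genes are not independent replicates. In estradiol the counts were 130 (114), 138 (106) and 382 (220). The test of the difference, MCF-7 minus T47D in vehicle, called 1845 genes higher and 1999 lower. EPHA4 differed by −7.13 (SE 0.383, adjusted p = 5.78e-09), KITLG by 5.24, RET by 5.10, NEO1 by 2.43, SLC7A5 by −4.16 and DKK1 by −4.23. Of 19 dependence receptor and netrin genes 5 were higher and 5 lower (6 and 5 adjusted over the list alone, camera adjusted p = 0.358). Of 35 interferon response genes 4 were higher, OAS3 (2.08) among them, and 8 lower, such as IFIT1 (−4.30), DDX58 (−1.79) and OASL (−3.57), or 4 and 9 adjusted over the list alone (camera adjusted p = 0.0814). Of 31 basal genes 6 were higher, such as KRT15 (3.78), and 9 lower, such as CAV1 (−5.92) and TAGLN (−5.61), the same adjusted over the list alone (camera adjusted p = 0.351). Of the luminal genes TFF3 differed by 4.09 and GATA3 by 2.32. BCL2 (0.99, SE 0.399, adjusted p = 0.0819) and TP63 (0.34, SE 0.643, adjusted p = 0.756) did not pass the test of a difference, and BCL2 passed it without MCF-7 control vehicle replicate 1, at 1.58. NTN4 passed at −0.95 (adjusted p = 0.0388), a call lost when any of 9 libraries was left out. Luminal genes (8 higher and 2 lower of 25, the same adjusted over the list alone, camera adjusted p = 0.0146, adjusted p = 0.188 with an estimated correlation) and Wnt targets (7 and 1 of 14, 9 and 1 adjusted over the list alone, 0.0119, adjusted p = 0.188 with an estimated correlation) stood higher in MCF-7, as did proliferation genes such as AURKA (1.76), 17 and 3 of 50 (19 and 3 adjusted over the list alone, 0.00144, adjusted p = 0.369 with an estimated correlation). Hypoxia genes such as LDHA (−1.74) stood lower, 3 higher and 13 lower of 26 (3 and 14 adjusted over the list alone, camera adjusted p = 0.00109, adjusted p = 0.102 with an estimated correlation). So did ribosomal protein genes such as RPL3 (−2.20), 0 and 25 of 50 (0 and 31 adjusted over the list alone, 1.28e-08, adjusted p = 0.454 with an estimated correlation), and ribosome biogenesis genes such as DKC1 (−2.31), 1 and 18 of 36 (1 and 22 adjusted over the list alone, 7.97e-08, adjusted p = 0.102 with an estimated correlation). The 3844 ran from 2598 without MCF-7 shRNA vehicle replicate 2 to 5524 without MCF-7 control vehicle replicate 1. Whether shRNA-labelled cells without hormone already differed in estradiol-responsive genes was tested with genes called in the control cells of the other line. The 267 genes induced and 113 repressed in MCF-7 did not move together in T47D (camera adjusted p = 0.783 and 0.436). The genes induced in T47D, 9 in number, had 5 lower members and 0 higher in MCF-7, at a camera adjusted p of 0.112. Their median log2 fold change was −0.867, in a comparison where 3019 of 15237 genes were lower. Tested by themselves with fry of limma, not against other genes, they had an unadjusted p of 0.000505. The 267 and 113 genes had fry p of 0.937 and 0.588 in T47D. The 9 genes were thus lower, but not shown to be lower than other genes.

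In the authors' deposited table of edgeR results, which has 26144 rows for 11670 gene symbols and no row for UNC5A, log2 fold changes correlated with those given here at r = 0.967 to 0.99 over the 6 comparisons it holds. Symbols were counted as up or down at the authors' adjusted p under 0.05, and a match with a gene called here needed the same direction. That table holds fewer symbols than the 15237 genes tested here, so some genes called here may have no row in it. In the authors' deposited table the MCF-7 knockdown comparison lists 1281 symbols up and 1745 down, of which 2812 are among the 5740 genes called here. For the T47D knockdown comparison the authors' deposited table lists 838 up and 1011 down, with 873 of the 1077 called here. For estradiol in MCF-7 control cells, where 267 genes rose and 113 fell here, the authors' deposited table lists fewer symbols up (81) than down (115), and 97 of the 380 called here are among them. For estradiol in MCF-7 shRNA-labelled cells the authors' deposited table lists 1445 up and 1624 down, with 728 of the 767 called here. For estradiol in T47D the authors' deposited table lists 110 up and 55 down in control cells and 190 up and 48 down in shRNA-labelled cells, which include the 9 and 7 genes called here.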

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

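The tests of T47D signal in 1 library, of GC content as the whole cause of its distance, of the UNC5A counts, of exchanged labels, of depth and of chromosome segments were chosen after the results they bear on were seen, and the other 3 before.

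The first group of results for a closer look is the difference between the estradiol responses of shRNA-labelled and control MCF-7 cells, where 4 genes passed the test of the difference itself, SPNS2 (4.29), TBKBP1 (3.36), PTGES (1.76) and GLCCI1 (−1.7). Each lost its call when any 1 of the MCF-7 libraries other than control vehicle was left out, for example at 4.32, 3.31, 1.89 and −1.81 without control estradiol replicate 1, and without several T47D libraries. The second is the difference between the control cells' estradiol responses in MCF-7 and T47D, where 33 genes passed. Among them were SLC26A2 (2.64), GREB1 (2.25), CA12 (2.35), SIAH2 (1.95), CCND1 (1.49) and NR5A2 (2.94), larger in MCF-7, the last 2 not called without T47D control estradiol replicate 1 (1.42 and 2.84). RIMS2 (−3.57), RNF43 (−1.8), BMF (−1.8) and PPP1R3C (−1.59) were smaller in MCF-7 and not called without MCF-7 control estradiol replicate 2 (−3.44, −1.94, −1.73 and −1.53) or certain other libraries. The third is the difference between lines of the vehicle effect of the shRNA label, where 3844 genes passed. EPHA4 (−7.13), SLC7A5 (−4.16), IFIT1 (−4.3), DDX58 (−1.79), OASL (−3.57), DKK1 (−4.23), CAV1 (−5.92), TAGLN (−5.61), LDHA (−1.74), RPL3 (−2.2), DKC1 (−2.31) and NTN4 (−0.95) were lower in MCF-7 relative to T47D, and RET (5.1), NEO1 (2.43), KITLG (5.24), KRT15 (3.78), TFF3 (4.09), GATA3 (2.32), OAS3 (2.08) and AURKA (1.76) higher. NTN4 lost its call when any 1 of 9 libraries was left out, at −0.6 without MCF-7 control vehicle replicate 1.

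MCF-7 control vehicle replicate 2 stood apart from replicate 1, with a chi-square per degree of freedom of 270 over genes, against 18.6 to 40.2 in the other 3 MCF-7 groups and up to 113 in T47D. The distance was 298 (others of MCF-7 at most 42.3) without genes rich in T47D, it fell to 64.2 (at most 13.3) without small RNA, and the variance of the log2 ratio fell from 0.473 (at most 0.13) to 0.31 (at most 0.0922) once its trend on GC content was removed, which argues against each of these as the whole cause and leaves small RNA open as a part. The first value kept small RNA rows not rich in T47D, and small RNA carried much of the distance. It therefore cannot tell how far T47D signal accounts for genes outside small RNA, and no test left out both. The GC test replaced a rank correlation of that ratio with GC content, which had met the bound set for a GC bias at 0.601 but was −0.591 in MCF-7 control estradiol and 0.59 in T47D shRNA estradiol, so a GC bias as part of the distance stays open. RNA or reads of T47D cells may be another part, since 33 genes abundant in T47D and low in the other 7 MCF-7 libraries, 28 of them highest in replicate 2, stood at a median of 3.29% of their T47D level (quartiles 2.28% and 4.28%) against medians of 0.377% to 0.593% and upper quartiles of at most 1.5% when the same choice was made for each other library. It stays open because the sum over the genes, the value set to decide, was 3.05% against 1.72% in replicate 1, under the 2-fold margin, because a choice for another library leaves out genes high in replicate 2, and because this was the last of 4 ways of choosing genes, where the others gave 3.05% against at most 0.717%, 10.9% against 9.13% and 3.27% against 1.16%, and no biological explanation was tested because the design gives none.

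UNC5A was not lower in the MCF-7 libraries labelled UNC5A shRNA. Counts too low to show a fall to 0.5 of the control are argued against in vehicle, where the lower limit of the exact ratio, scaled by library size, was 1.44, though that limit covers counting error only and the control replicates held 1 and 7 reads. Exchanged control and shRNA labels in MCF-7 cannot be told apart from correct labels with unlike effects in the lines. Of 826 genes called one way in both T47D comparisons, 646 had 1 sign in both MCF-7 comparisons, and 47.1% of these had the sign of T47D, between the 30% and 60% set as bounds. An shRNA that acts on protein, loss of the knockdown in culture and a response of the gene to the shRNA cells' state were not tested.

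More genes differed between shRNA-labelled and control cells in MCF-7 (5740 in vehicle and 4477 in estradiol) than in T47D (1077 and 1500), but fits on each line's own 8 libraries gave 4441 against 2104 in vehicle and nearly equal numbers in estradiol, 3272 against 3174. Greater depth is argued against by a median count without small RNA in MCF-7 of 0.608 of that in T47D, and GC content by the ratio of genes beyond a log2 fold change of 1 in estradiol, 2.48 before and 3.19 after the GC trend was removed (1526 in MCF-7 and 478 in T47D). Chromosome segments in different copy number in the MCF-7 control and shRNA cells are a candidate explanation for part of it, because medians over 176 windows of 50 neighbouring genes had an SD of 0.339 in vehicle and 0.333 in estradiol, above each of 100 shuffled gene orders (at most 0.138 and 0.12), and correlated at r = 0.948 between the treatments. That correlation would follow from any stable difference. Neighbouring genes that share regulation could widen the medians too, which was not tested. The 4 estradiol responses, which compare cells of 1 kind, exceeded their shuffled orders narrowly (0.0301 to 0.0717 against at most 0.0299 to 0.0645). T47D windows of the label also exceeded shuffled orders (0.13 and 0.131 against at most 0.0648 and 0.0665), in part in adjoining windows given below. Segments may differ in T47D as well, so T47D does not tell these explanations apart. Loss of UNC5A, the hairpin, the clone and separate culture go with the label and stay open, untested.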

How the results depend on the processing

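The fits without small RNA, lists without MCF-7 control vehicle replicate 2 and overlaps of shRNA effects at 0.01 were chosen after the data were seen, and all other alternatives before. With groups of 2 libraries the estimate of spread is imprecise, and small changes at low counts may have been missed, though recovery by count level was not measured. The cause of the shifts listed here was not tested. A fit on 1 line or without a library holds fewer samples, and a stricter threshold fewer genes. Either can lower a count, but fewer samples do not account for counts that rose. Estradiol in MCF-7 control cells called 380 genes, but 1426 without the low-count filter, 201 with the replicate block, 81 from the 8 libraries of the line and 835 by DESeq2. In MCF-7 shRNA-labelled cells 767 became 1206 without the filter and 338 from the line's libraries. The MCF-7 difference, 4, became 427 without the filter, 0 with the replicate block, 0 from the line's libraries, 170 by DESeq2 and 7 without small RNA. In T47D control cells 9 became 109 without the filter, 1 with the replicate block, 28 from the line's libraries and 45 by DESeq2, and in T47D shRNA-labelled cells 7 became 70, 0, 24 and 39. The T47D difference, 0, became 27 without the filter. For the label in T47D, 1077 in vehicle became 2104 from the line's libraries, and 1500 in estradiol became 3174, or 2322 without the filter, while for MCF-7 5740 became 4441 and 4477 became 3272 from the line's libraries. The difference of estradiol responses between lines, 33, became 793 without the filter, 15 with the replicate block and 198 by DESeq2. DESeq2 lowered the share of higher calls from 70.3% to 55.3% in MCF-7 control cells, from 75% to 48.8% in the MCF-7 difference, from 100% to 64.4% in T47D control cells and from 87.9% to 72.7% between lines, and without small RNA the MCF-7 difference had 85.7% and T47D control cells 81.8%. At an adjusted p of 0.01 the overlap of MCF-7 control and shRNA-labelled responses fell from 200 to 85, that in T47D from 3 to 0, and those between lines from 6 to 1 in control and from 6 to 1 in shRNA-labelled cells. Overlaps of the label's effects fell from 3206 to 1921 between treatments in MCF-7 and from 826 to 373 in T47D, and between lines from 277 to 92 in vehicle and from 268 to 89 in estradiol. The ribosomal protein list under estradiol in MCF-7 control cells reversed without control vehicle replicate 2, with an adjusted p of 1.9e-06 against 0.0106 in the main result, 0.00603 with the replicate block and 0.736 with an estimated correlation.

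Leaving out 1 library at a time gave 96 to 4455 genes for estradiol in MCF-7 control cells, 315 to 1608 in MCF-7 shRNA-labelled cells and 0 to 3021 for their difference. It gave 0 to 48 in T47D control cells, 0 to 40 in T47D shRNA-labelled cells and 0 to 0 for their difference. For the label it gave 3673 to 7003 in MCF-7 vehicle, 2695 to 5903 in MCF-7 estradiol, 401 to 2101 in T47D vehicle and 403 to 3170 in T47D estradiol. Between lines it gave 7 to 3847 for the estradiol response and 2598 to 5524 for the label. The common dispersion, 0.0361, was 0.0215 without either MCF-7 control vehicle replicate and 0.0358 to 0.04 without any other library. The spread of that MCF-7 pair thus enters the tests of T47D in the fit over all 16 libraries. Each T47D count that rose was highest without a library of that pair. Deviations of same-numbered libraries correlated at −0.16 to 0.15 over 12 pairs of groups, so no pairing by replicate number showed. Trends on GC content that differ between libraries could hide a pairing. Whether calls lost under the block are weaker effects therefore stays open. Of the 227 log2 fold changes named, 200 of them called, 14 changed sign under some alternative, 0 of these called in either, PGR between lines (−0.26 and 1.40) among them. Over the fits with 1 library left out, 3341 of their values kept their side of the threshold, 281 lost and 10 gained a call. With the replicate block 199 kept theirs and 28 lost it, and by DESeq2 221 kept theirs and 2 gained a call. No scaling moved the median of all genes by over 0.1.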

Other observations

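In T47D vehicle 4 of 19 replication-dependent histone genes rose and 0 fell, HIST1H4C by 1.27 and HIST1H3D by 0.99 among them (5 and 0 adjusted over the list alone, camera adjusted p = 2.6e-05, adjusted p = 0.182 with an estimated correlation), and in estradiol 5 rose and 0 fell (7 adjusted over the list alone, camera adjusted p = 0.00138, adjusted p = 0.31 with an estimated correlation). Without MCF-7 control vehicle replicate 2, 8 rose in vehicle and 8 in estradiol. Histone genes form families with near-identical copies, so counts of single members are uncertain. Of 18 epithelial-mesenchymal transition genes in MCF-7 vehicle 4 rose and 6 fell, the same adjusted over the list alone, with TWIST1 (3.85) up and TGFB2 (−5.62) down and vimentin (VIM) at 109 against 2 reads, a ratio scaled by library size of 39.5 (10.7 to 330), and the list did not pass camera (adjusted p = 0.938). In T47D vehicle 1 of the 18 rose and 0 fell (1 and 1 adjusted over the list alone, camera adjusted p = 0.901), and 2 rose and 2 fell without MCF-7 control vehicle replicate 2. Of 26 apoptosis genes in MCF-7 vehicle 7 rose and 5 fell (7 and 6 adjusted over the list alone, camera adjusted p = 0.878). These directions in MCF-7 rest on the shRNA label, not on a lower UNC5A count.

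Genes present in one kind of cell and close to absent in the other were counted, taking at least 400 summed reads and a 100-fold difference. These were plain reads, not scaled by library size. MCF-7 libraries held 14857164 to 17141876 counts with the shRNA label and 11137945 to 15973652 in control. T47D libraries held 24760382 to 37140696 and 19293298 to 24762438. The rule therefore finds genes of shRNA-labelled cells more easily, and the split between the 2 kinds is not a result. In MCF-7 there were 58, of which 16 were seen in control and 42 in shRNA-labelled libraries, and in T47D 7, all in shRNA-labelled libraries. MTAP, on chromosome 9 from 21802635 to 21865969 and chosen after its values were seen, was at 1.44 to 5.51 CPM in the 8 MCF-7 libraries and at 43.4 to 67.9 CPM in the 8 T47D libraries.

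The windows of 50 neighbouring genes named here were chosen after their values were seen. In MCF-7 many windows had a shifted median log2 fold change of the shRNA label, with the GC trend removed, and those given are examples. The largest in vehicle lay on chromosome 7 from 86974951 to 99517223 (−1.02 in vehicle, −0.93 in estradiol) and from 99564350 to 105753093 (−0.9 and −0.94), on chromosome 20 from 49126858 to 62258381 (0.9 and 0.76) and on chromosome 19 from 40946748 to 45650543 (0.88 and 0.81). Further windows on chromosome 19 from 50180409 to 53997546 and from 54024177 to 58446740 stood at 0.81 and 0.76 in vehicle. Adjoining windows on chromosome 12 from 59265937 to 133684258 stood at 0.39 to 0.75 in vehicle and 0.35 to 0.7 in estradiol. Those on chromosome 15 from 22833395 to 83736106 stood at 0.27 to 0.58 and 0.25 to 0.64. On the X chromosome the window from 131503343 to 153679002 stood at −0.8 and −1.01 in MCF-7 and at 0.54 and 0.64 in T47D, and the window from 103411156 to 131353508 at −0.38 and −0.37 in MCF-7 and at 0.77 and 0.7 in T47D. The adjoining window from 70835766 to 103087212 stood at 0.17 and 0.29 in MCF-7 and at 0.69 and 0.71 in T47D. In T47D, adjoining windows on chromosome 6 from 292057 to 56920037 stood at 0.23 to 0.32 in vehicle and 0.27 to 0.34 in estradiol. Those on chromosome 22 from 36863093 to 51021428 stood at 0.24 to 0.34 and 0.28 to 0.3. The T47D window on chromosome 4 from 53179 to 8442452 stood at −0.37 and −0.38. Window medians of the estradiol responses had an SD of 0.0594 in MCF-7 control cells (at most 0.056 in shuffled orders), 0.0717 in MCF-7 shRNA-labelled cells (0.0645), 0.0479 in T47D control cells (0.0437) and 0.0301 in T47D shRNA-labelled cells (0.0299), and those of control and shRNA-labelled cells correlated at r = 0.312 in MCF-7 and 0.364 in T47D. Window medians of the label correlated between lines at r = −0.229 in vehicle and −0.189 in estradiol, across windows, which are not replicates.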
